A study of Homo sapiens with 7 samples.

How the data were processed

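RNA from immunoprecipitates of cytoplasmic BEAS-2B lysates was measured on 7 Illumina HumanRef-8 v3 BeadChip arrays, 3 with an antibody against GR and 4 with control IgG. Groups and replicate numbers were taken from the labels, which name replicates 2, 3 and 4 for GR-IP and 1 to 4 for IgG-IP. The labels' antibody field names the control as rabbit IgG, while their description names mouse IgG, so the species of the control antibody is not settled. Per the labels' protocols, RNA was extracted from the beads, reverse transcribed with an oligo-dT primer and amplified to biotin-labelled RNA.

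The deposited table holds 1 value of probe intensity per array, the mean bead intensity on a linear scale. The authors exported it from BeadStudio 3.4.0 with normalization set to none and without background subtraction, per the file headers. The table also holds a detection p-value per probe and array, which the authors' software set from the negative control beads of the array, per the file headers, in 664 equal steps as the values show. All value columns were matched to a sample by name, and 0 value columns were left over. Slides, scan dates and control probes were not used here, so no test of slide as a batch was run.

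Gene symbols came from the table and were updated through Entrez gene numbers and accessions against the RefSeq gene table of assembly GRCh38.p14, which was used for names only. Of 24526 probes 24186 (98.6%) matched, and 4062 symbols were updated. The table gives probe coordinates without naming a genome build, so they are not printed. The 75 probes on the Y chromosome or for XIST were left out of names and lists. Each probe is 50 bases long. Genes had more than 1 probe in 3906 cases. Counts are of probes, a named gene is given by its probe with the largest change among those called, and lists use the probe with the highest mean. MED15 alone had probes called in both directions.

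Background was corrected with normexp, using detection p-values in place of control probes, with an offset of 16, followed by quantile normalization between arrays and log2, which is the neqc procedure of limma 3.58.1 in R 4.3.3. Probes with a detection p under 0.01 on at least 3 of the 7 arrays were tested, which left 6899 probes of 6228 genes. Group differences were fitted with limma (lmFit and eBayes), and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. All adjusted p-values of single genes are from limma unless another test is named. A log2 fold change is GR-IP minus IgG-IP, on a scale whose offset makes the change of dim probes smaller than it is. A gene detected on no IgG-IP array has only a bound, computed as its mean in GR-IP over the mean, per IgG-IP array, of the higher of the dimmest detected signal and the probe's own. Where this bound was under 1, intensities are given without a fold. Because quantile normalization gives every array the same distribution, a probe called lower is lower relative to the other probes.

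The 19 gene lists, the list test, most alternative settings and the rule for named genes were fixed before the data were examined. Lists were tested with camera at a preset correlation of 0.01, and a list with under 5 tested members was described only. The rule named NR3C1, CCL2, CCL7, GAS5 and SRA1 in any case. It added the 10 largest rises and the 10 largest drops among probes past the threshold with no overlap between the groups, 1 probe per gene, leaving out symbols of the LOC kind and open reading frame names. From each list past the threshold or with at least 3 members called it added up to 4 members with the smallest p. Measures per array were compared with a two-sided exact permutation test of the difference of means over all 35 splits of the arrays.

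Alternatives changed 1 choice at a time. They covered the background correction, the offset (50), the between-array normalization, the detection filter, the replicate number as a block, array weights, trend and robust moderation, a size threshold, an unequal-variance test per probe, the set test and leaving out each array. Values without between-array normalization, median centring on the tested probes and removal of the trend on probe GC content were added after seeing the data. The planned analysis of GC content and length of transcript parts was not run, because transcript sequences were not used here.

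The pipeline was tested on simulated arrays with 7699 tested probes and known changes. Of 50 probes changed by a log2 fold change of 1, 30% were called, and 14% of 50 changed by -1. The shares were 92% for 2 and 90% for -2. Only 1 unchanged probe was called. The simulated noise was independent between probes, with 1 replicate SD of 0.28 log2 units for every array. These shares therefore do not measure missed or false calls on the real arrays. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, statsmodels 0.14.6 and matplotlib 3.10.9 handled tables, array tests and figures.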

Results

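RNA recovered with an antibody against the glucocorticoid receptor (GR), a ligand-activated transcription factor, was measured in BEAS-2B cells. These are an established human airway epithelial line immortalised with an adenovirus 12-SV40 hybrid virus. Cytoplasmic lysates were immunoprecipitated with an antibody against GR (GR-IP, n = 3 arrays, replicates 2, 3 and 4) or with control IgG (IgG-IP, n = 4 arrays, replicates 1 to 4). The recovered RNA was amplified from oligo-dT, labelled and hybridised to Illumina HumanRef-8 BeadChips, with 1 array per immunoprecipitation and 24526 probes per array. The series asks which transcripts are associated with GR and which RNA motif they share. The motif was not analysed here, because no transcript sequences were used. The labels do not say that the replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. The number of arrays limits the precision.

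The GR-IP arrays held more transcripts above background than the IgG-IP arrays. A mean of 7696 ± 566 probes (SD, n = 3) was detected in GR-IP at a detection p under 0.01, and 4708 ± 1046 probes (SD, n = 4) in IgG-IP. The difference of 2987 probes exceeded the spread between arrays (two-sided exact permutation test over 35 splits, p = 0.0286, the smallest this design allows; 0.0381 after Benjamini-Hochberg adjustment over 8 array measures). The median probe intensity lay at background in both groups, at 54.0 ± 0.64 in GR-IP and 52.6 ± 1.11 in IgG-IP, and the difference did not exceed the spread between arrays (two-sided exact permutation p = 0.171, adjusted 0.196). The bright end of the arrays separated the groups. The 99th percentile of intensity was 1585 ± 738 in GR-IP and 375 ± 118 in IgG-IP, a ratio of 4.23 (exact permutation p = 0.0286). All 3 GR-IP and all 4 IgG-IP arrays detected 3110 probes. A further 900 probes were detected on all 3 GR-IP arrays and on no IgG-IP array. Only 2 probes, for ABCC2 and LOXL3, showed the opposite, and both genes are named after their values were seen. Log2 intensities correlated across probes at 0.962 to 0.981 between GR-IP arrays, 0.964 to 0.980 between IgG-IP arrays and 0.880 to 0.964 between the groups. Probes are not independent replicates.

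**Figure D1:**
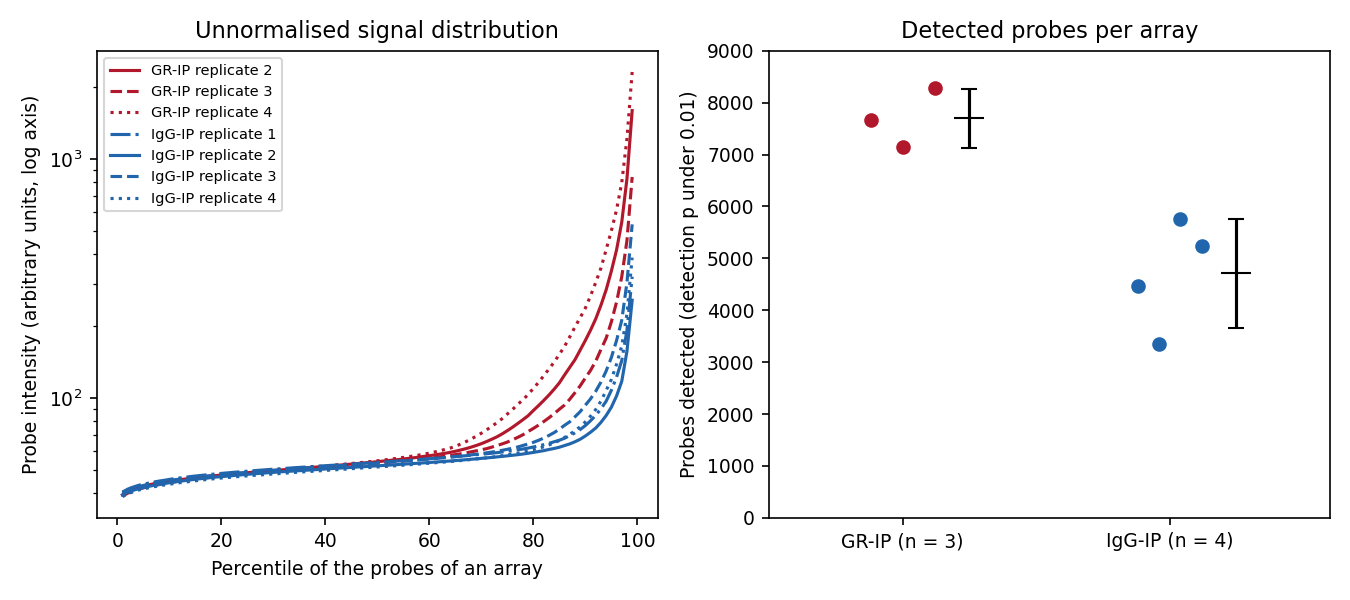
Left, unnormalised probe intensity (arbitrary units, log axis) at each percentile of the probes of an array, with GR-IP in red, IgG-IP in blue and 1 line style per replicate. Right, probes detected per array at a detection p under 0.01, with mean and SD beside the points: the 3 GR-IP arrays sit between 7146 and 8277, above the 4 IgG-IP arrays at 3359 to 5765.

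Against this general rise, a smaller set of probes was called higher or lower relative to the rest of the array. After quantile normalization, which removes the difference in overall signal, 413 of 6899 tested probes (404 genes) were higher in GR-IP, and 234 probes (233 genes) were lower relative to the other probes of the same array, whereas without between-array normalization 6143 probes were higher and 0 were lower (limma, Benjamini-Hochberg adjusted p under 0.05). At an unadjusted p under 0.05 limma gave 1213 higher and 701 lower probes after quantile normalization, and 6200 higher and 0 lower without it. After background correction and without between-array normalization the typical tested probe was 2.71-fold brighter in GR-IP, a median log2 fold change of 1.44. Probes called higher had a median of only 1.58 on that scale, and some rose less than the typical probe, such as HSPA1B with 1.12. Uncorrected intensities had medians over tested probes of 128 in GR-IP and 68.6 in IgG-IP. The changes given for single genes below are relative to such a rise. The labels name a single amount of RNA for every amplification, with a unit that looks incomplete, so it is not settled whether overall brightness follows the amount of RNA recovered or its polyadenylated share. The median was 0.07 after quantile normalization, 1.33 after median centring and 0.35 after z-scoring of each array. The split of the calls followed the scaling: 5950 higher and 0 lower with median centring, 2318 and 478 with z-scores, 225 and 285 with cyclic loess, and 1060 and 1348 with median centring on the tested probes. Of the 413 higher and 234 lower calls these scalings kept, in the same order, 413 and 0, 409 and 109, 183 and 216, and 109 and 185. Other choices moved the counts too: 40 higher and 132 lower when detection on all 7 arrays was required, 102 and 72 with an offset of 50, 277 and 142 without background correction, 245 and 106 with the replicate number as a block, 1072 and 660 with array weights, 647 and 259 with trend and robust moderation, and 6 and 0 in an unequal-variance test per probe (846 and 563 unadjusted). The counts also changed when 1 array was left out. This leaves the test fewer arrays, so a lower count need not mean that the array left out drove the calls. They came to 15 higher and 0 lower without GR-IP replicate 2, 57 and 20 without replicate 3 and 31 and 3 without replicate 4. At an unadjusted p under 0.05 in limma they were 1003 and 553, 1043 and 700, and 885 and 546, in the same order. They came to 177 and 75 without IgG-IP replicate 1, 256 and 134 without replicate 2 and 217 and 110 without replicate 4.

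**Figure D2:**
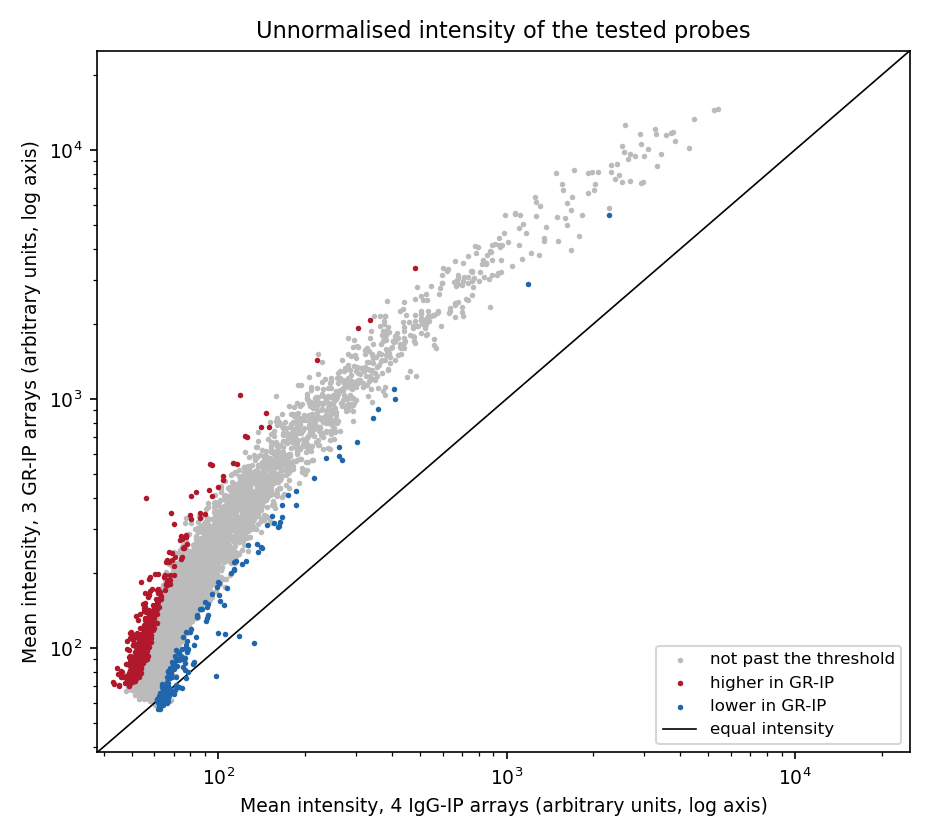
Mean unnormalised intensity of each of the 6899 tested probes in the 4 IgG-IP arrays (horizontal) and the 3 GR-IP arrays (vertical), both in arbitrary units on log axes, with probes called higher in red, probes called lower in blue and a line of equal intensity. Probes called lower had a median intensity of 67.1 in IgG-IP and 69.6 in GR-IP, so that many lie near the line at the dim end, while brighter ones such as HSP90AA1 (408 in IgG-IP and 994 in GR-IP) lie above it. Probes called higher had medians of 54.7 in IgG-IP and 101 in GR-IP.

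The largest rises among the genes the naming rule admits were those of TLE5, DYNLRB1, TAF6, HLA-E, RAB43, UCP2, ING2, WDR45B, NDST1 and CAMK2N1. Of the 413 probes called higher, 262 were detected on no IgG-IP array, so for such genes the change is given as a lower bound. TLE5, a Groucho-related corepressor that the file lists as AES, was at least 2.23-fold higher, with an intensity of 184 ± 36.4 (SD, n = 3) in GR-IP against 54.0 ± 5.88 (SD, n = 4) in IgG-IP (limma adjusted p = 0.00287). TAF6, a subunit of the general transcription factor TFIID, was at least 2.31-fold higher (adjusted p = 0.00641), and RAB43, a small GTPase of membrane traffic, at least 2.26-fold higher (adjusted p = 0.00720). HLA-E, a nonclassical class I antigen, was at least 1.70-fold higher (adjusted p = 0.00342). WDR45B, an autophagy protein listed as WDR45L, was at least 1.97-fold higher (adjusted p = 0.0113), and ING2, a reader of histone methylation, at least 1.58-fold higher (adjusted p = 0.00287). CAMK2N1, an inhibitor of calmodulin-dependent kinase II, was detected on all 7 arrays and rose by 1.54 ± 0.18 on the log2 scale (SE, adjusted p = 0.00287), from an intensity of 119 ± 28.6 in IgG-IP to 1038 ± 602 in GR-IP. UCP2, a carrier of the inner mitochondrial membrane, was also detected on all 7 arrays, with a log2 fold change of 1.63 ± 0.24 (adjusted p = 0.00720). DYNLRB1, a dynein light chain, had a log2 fold change of 1.79 ± 0.23 (adjusted p = 0.00366, detected on 1 IgG-IP array). NDST1, an enzyme of heparan sulfate synthesis, had 1.60 ± 0.27 (adjusted p = 0.0122, detected on 2 IgG-IP arrays). All 3 GR-IP arrays lay above all 4 IgG-IP arrays for each of these 10 genes, as the rule for naming them required, and chance gives such a separation for 1 gene in 35. Each kept a positive log2 fold change under every scaling tried. Without GR-IP replicate 2 the calls of TAF6, RAB43, WDR45B and NDST1 ended (adjusted p = 0.0511 to 0.0600), and without GR-IP replicate 3 that of NDST1 did (adjusted p = 0.0534).

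The transcripts called lower also lay below the typical tested probe without between-array normalization, which their choice on the same arrays made nearly certain. Without between-array normalization their log2 fold changes had quartiles of -0.0079 and 0.70 and reached 1.41, all below the median of 1.44 over all tested probes, and 61 of the 234 lay below 0, none past the threshold. TRIM16L had the largest drop, with a log2 fold change of -2.19 ± 0.43 (SE, limma adjusted p = 0.0187), yet its intensity was 104 ± 27.0 in GR-IP (SD, n = 3) and 133 ± 19.8 in IgG-IP (SD, n = 4), and its log2 fold change of -0.53 without between-array normalization did not pass the threshold. TPM3, a tropomyosin, had -1.98 ± 0.41 (adjusted p = 0.0210) and SALL3, a zinc finger transcription factor, had -1.83 ± 0.28 (adjusted p = 0.00759). TRIM16L is nearly identical to TRIM16, and TPM3 has processed pseudogenes, so their probes may read more than 1 transcript. FGA, the fibrinogen alpha chain, had -1.55 ± 0.26 (adjusted p = 0.0113), and CENPH, a kinetochore protein, had -1.43 ± 0.28 (adjusted p = 0.0187). PPID, MAP1A, P2RX7, SNHG10 and TP53BP2 followed, with log2 fold changes of -1.34, -1.31, -1.30, -1.28 and -1.27 (adjusted p from 0.0163 for MAP1A to 0.0418 for TP53BP2). All 10 lay below IgG-IP on every GR-IP array after quantile normalization, as the rule for naming them required. Without between-array normalization none of the 10 passed the threshold, and FGA, CENPH, MAP1A, P2RX7, SNHG10 and TP53BP2 turned to positive values of 0.016 to 0.27. All 10 calls ended without GR-IP replicate 2, and all but that of SALL3 without GR-IP replicate 4.

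**Figure D3:**
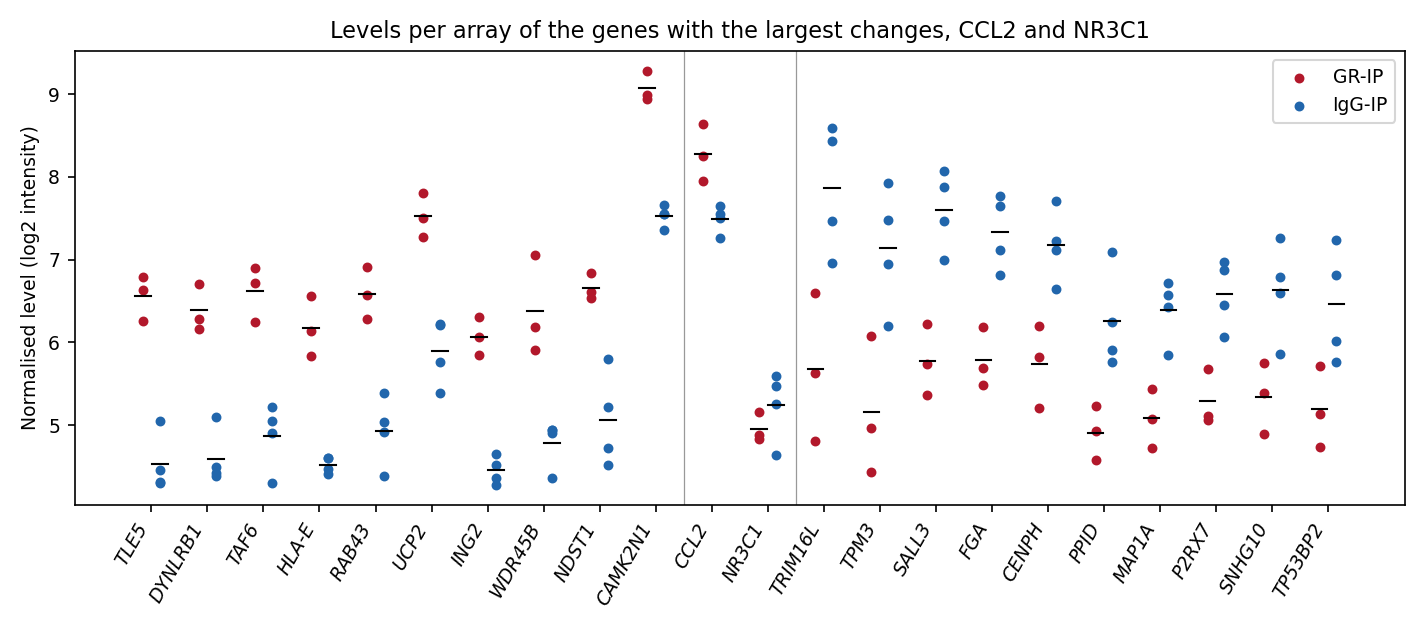
Quantile-normalised level (log2 intensity, vertical) of single genes (horizontal) on each GR-IP array (red) and IgG-IP array (blue), with a black bar at each group mean. The left block holds the 10 largest rises (TLE5 to CAMK2N1), the middle CCL2 and NR3C1, and the right the 10 largest drops (TRIM16L to TP53BP2), which are drops relative to the other probes and do not pass the threshold without between-array normalization.

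CCL2, the chemokine that recruits monocytes, was among the transcripts called higher. Its intensity was 546 ± 129 in GR-IP (SD, n = 3) and 116 ± 24.2 in IgG-IP (SD, n = 4), and its log2 fold change was 0.79 ± 0.21 (SE, limma adjusted p = 0.0391), or 2.69 without between-array normalization. Leaving out any 1 array except IgG-IP replicate 2 ended the call, with log2 fold changes of 0.60 to 0.93, and the adjusted p over all alternatives ran from 0.000129 to 0.226. NR3C1, the gene that encodes GR, was not called: the probe that was tested had a log2 fold change of -0.28 ± 0.24 (adjusted p = 0.476), which ranged from -0.85 with median centring on the tested probes (adjusted p = 0.00511) to 0.58 without between-array normalization (adjusted p = 0.0492), 2 scalings chosen after seeing the data. It was also positive with median centring (0.47) and z-scores (0.048), where it did not pass, and its adjusted p reached 0.839 over the alternatives. The tested NR3C1 probe was dim, at 72.9 ± 6.49 in GR-IP (SD, n = 3) and 61.2 ± 4.57 in IgG-IP (SD, n = 4). It was detected on all 3 GR-IP arrays and 2 IgG-IP arrays. The other 2 NR3C1 probes were detected on no array, so the result for this gene rests on that dim probe. CCL7, a related monocyte chemokine, was detected on no array. SRA1, the steroid receptor RNA activator, was detected on 1 GR-IP array and no IgG-IP array and was not tested. No probe carries the symbol GAS5.

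Genes induced by glucocorticoids had a median log2 fold change of 0.36 over 13 tested members, 0.31 above the other genes. This was the highest median of the 19 fixed gene lists in the main analysis, but the list did not keep the largest shift with median centring, with z-scores or without a filter. The shift did not pass the threshold (camera adjusted p = 0.383 over 18 tested lists, unadjusted 0.0213, and adjusted p = 0.979 with an estimated correlation). In this list 2 members were higher and 0 were lower, and 5 were higher when adjusted over the list alone. The 2 were MT1X, a metallothionein with a log2 fold change of 0.88 ± 0.20 (SE, limma adjusted p = 0.0270), and ZFP36, an mRNA decay factor that binds AU-rich elements, with 0.85 ± 0.23 (adjusted p = 0.0444, detected on 1 IgG-IP array). MT1X was chosen after its values were seen, as were the other list members named below that are given without a value. In the main analysis none of the 18 tested lists passed the threshold with camera, with an estimated correlation or with fry. This depended on the scaling and the filter. With median centring 4 lists shifted up and 2 down, with z-scores 0 up and 4 down, and 1 shifted up when detection on all 7 arrays was required. At an unadjusted p under 0.05 the glucocorticoid-induced list alone passed camera.

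Among the chaperones and cochaperones that hold GR in the cytoplasm, members went both ways. Of 17 tested, 2 were higher and 2 lower (3 and 3 adjusted over the list alone, camera adjusted p = 0.979). DNAJB1 rose by 0.70 ± 0.20 on the log2 scale (limma adjusted p = 0.0483, detected on 1 IgG-IP array). HSPA1B, whose near-identical copy HSPA1A its probe may not tell apart, was detected on all 3 GR-IP and no IgG-IP arrays, at intensities of 77.7 ± 15.0 and 49.8 ± 2.35 (adjusted p = 0.0383), and turned to -0.31 with median centring on the tested probes. HSP90AA1 was lower after quantile normalization (-0.84 ± 0.23, adjusted p = 0.0418) and higher, at 1.27 and past the threshold, without between-array normalization. PPID, a cyclophilin that binds HSP90, was the other member called lower. The HSP90AA1 call ended without any 1 of the 7 arrays, those of DNAJB1 and HSPA1B without any 1 array except IgG-IP replicate 3, and that of PPID without any 1 GR-IP array. The DNAJB1 call held in 6 of 21 alternatives.

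In the mRNA decay factor list, 2 of 28 tested members were higher and 1 was lower (2 and 1 adjusted over the list alone, camera adjusted p = 0.979). UPF1, the helicase of nonsense-mediated decay, was at least 1.26-fold higher (limma adjusted p = 0.0191), with 123 ± 42.3 in GR-IP against 55.0 ± 3.80 in IgG-IP. ZFP36 is the other member that rose. XRN1, a cytoplasmic exonuclease, was lower (-0.97 ± 0.21, adjusted p = 0.0230), but had 0.63 without between-array normalization. ZC3H12A, a cytoplasmic RNase, had 0.75 ± 0.25 and did not pass (adjusted p = 0.0758). Without GR-IP replicate 2 or 4 the calls of UPF1 and XRN1 ended, and that of ZFP36 ended without any 1 array except IgG-IP replicate 3.

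Transcripts of the translation machinery were abundant in both groups, and few stood apart. Of 75 tested cytosolic ribosomal protein genes, 3 were higher and 0 lower (2 and 0 adjusted over the list alone). RPL12 had a log2 fold change of 0.79 ± 0.18 (limma adjusted p = 0.0266) and RPL7 had 0.95 ± 0.26 (adjusted p = 0.0441, detected on 1 IgG-IP array), while RPL36A was detected on no IgG-IP array and had intensities of 90.8 ± 27.2 and 53.2 ± 2.85 (adjusted p = 0.0266). RPL12 turned to -0.28 with z-scores, and RPL36A to -0.070 with median centring on the tested probes. RPL14 had 0.68 ± 0.20 and did not pass (adjusted p = 0.0526). The RPL7 call ended without any 1 array except IgG-IP replicate 3, that of RPL12 without any 1 array except IgG-IP replicate 2 or 3, and that of RPL36A ended without any 1 GR-IP array. Ribosomal protein genes have many processed pseudogenes, so these probes may read more than 1 locus. The list's relative shift was 0.03 (camera adjusted p = 0.971), and it was 0.53 and past the threshold without between-array normalization and -1.31 and past it with z-scores. Of 53 translation factors, 2 were higher (2 over the list alone), EIF1B and EIF4H, and 0 lower. Of 67 oxidative phosphorylation subunits, NDUFB6 was higher and NDUFS7 lower (0 and 0 over the list alone), and of 40 proteasome subunits, PSMA3 was higher (0 over the list alone).

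The ZNF-named zinc finger genes, mostly DNA-binding regulators, are the largest list, with 8 of 132 tested members higher and 2 lower (8 and 2 adjusted over the list alone, camera adjusted p = 0.979). The list turned to a downward shift of -0.34 with median centring (camera adjusted p = 0.0278) and without between-array normalization (camera adjusted p = 0.0257). The share of members called, 7.58%, compares with 9.38% of all tested probes, a difference that was not tested. ZNF219 rose by 1.25 ± 0.21 on the log2 scale (limma adjusted p = 0.0112), and ZNF444 by 1.43 ± 0.27 (adjusted p = 0.0163, detected on 1 IgG-IP array). ZNF263 was detected on no IgG-IP array, with 83.5 ± 17.3 against 51.2 ± 0.94 (adjusted p = 0.0232), and turned to -0.16 with median centring on the tested probes. ZNF660 was lower (-1.26 ± 0.20, adjusted p = 0.00839), with 65.2 ± 2.95 against 70.0 ± 3.35 before normalization. All 4 calls ended without GR-IP replicate 2, those of ZNF263, ZNF444 and ZNF660 without replicate 4, and that of ZNF263 without replicate 3.

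Among noncoding RNAs, snoRNA host genes went both ways. Of 6 tested members of the nuclear-retained and noncoding list, 1 was higher and 2 lower (1 and 2 adjusted over the list alone, camera adjusted p = 0.728). The list passed with a downward shift of -0.75 with median centring (camera adjusted p = 0.0248) and without between-array normalization (camera adjusted p = 0.0257). SNHG5 had a log2 fold change of 1.01 ± 0.26 (limma adjusted p = 0.0373, detected on 2 IgG-IP arrays). SNHG3 had -0.96 ± 0.24 (adjusted p = 0.0343) and turned to 0.018 without between-array normalization, where SNHG10 had 0.20. RN7SK, the scaffold RNA of a transcription elongation inhibitor, had -0.30 ± 0.22 and was not called (adjusted p = 0.407). It ranged from -0.65 with median centring on the tested probes (adjusted p = 0.0181, a scaling chosen after seeing the data and the only alternative in which it passed, with adjusted p up to 0.795 in the others) to 0.78 without between-array normalization, and was 0.67 with median centring and 0.13 with z-scores. The calls of SNHG3 and SNHG5 ended without any 1 array except IgG-IP replicate 3.

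No list of cell identity markers passed the test. Of 15 tested extracellular matrix and mesenchymal genes, 2 were higher and 1 lower (3 and 1 adjusted over the list alone, camera adjusted p = 0.979). BGN, the proteoglycan biglycan, rose by 1.07 ± 0.25 on the log2 scale (limma adjusted p = 0.0266), and LAMA5, a laminin chain, by 0.82 ± 0.18 (adjusted p = 0.0237, detected on 1 IgG-IP array). CDH2, N-cadherin, was lower (-0.76 ± 0.22, adjusted p = 0.0491) but had 1.03 without between-array normalization. The CDH2 call ended without any 1 of the 7 arrays, and those of BGN and LAMA5 without any 1 GR-IP array or IgG-IP replicate 1. CCN1, listed as CYR61, had 0.82 ± 0.25 and did not pass (adjusted p = 0.0567). Of 13 epithelial markers, KRT80 was higher and KRT18 lower (5 and 1 over the list alone, camera adjusted p = 0.971). Of 29 immune and blood cell markers on the array only 2 were tested, and 0 were called.

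The remaining lists held few calls. Of 8 tested chemokines and cytokines, CCL2 was higher and CCL5 lower (1 and 1 adjusted over the list alone). Of 14 NF-kB target genes, NFKBIB was higher (0 over the list alone), and of 16 immediate early regulators, ID1 and ATF3 were higher (2 higher and 1 lower over the list alone). Of 30 mitotic genes, TPX2 was higher and BUB3 lower (1 and 1 over the list alone), and of 6 histones, H2AC18 was higher (1 higher and 1 lower over the list alone). No member of the 19 tested ER chaperones or of the 19 housekeeping genes was called in limma. The median, mean and test of a list differed in sign for 7 lists: GR chaperones, housekeeping genes, mitotic genes, NF-kB targets, proteasome subunits, histones and translation factors. Of the list members named as lower without a value, CCL5 (0.052), BUB3 (1.32) and NDUFS7 (1.41) had positive log2 fold changes without between-array normalization, and KRT18 had -0.060, which did not pass the threshold.

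**Figure D4:**
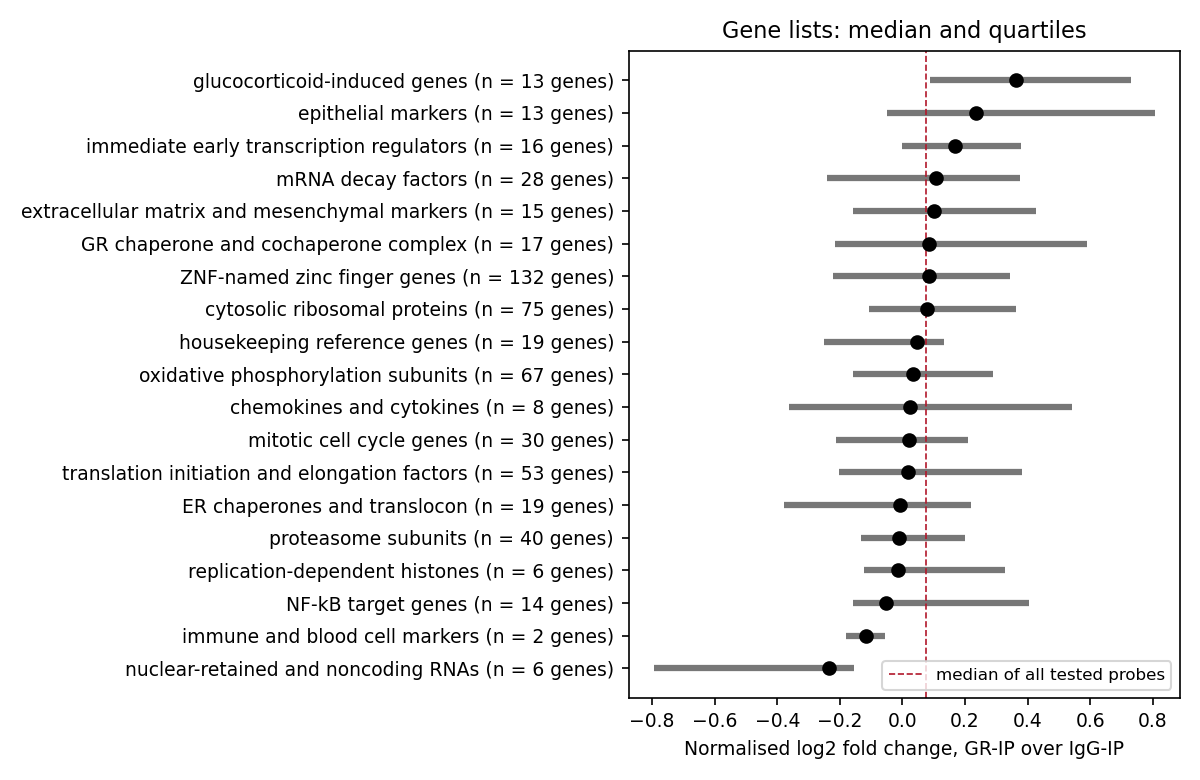
Median (point) and interquartile range (bar) of the quantile-normalised log2 fold change, GR-IP over IgG-IP (horizontal), of the tested members of each gene list (vertical, with the number of tested genes), with the median of all tested probes, 0.07, as a dashed line. The glucocorticoid-induced list has the highest median, 0.36, and the nuclear-retained and noncoding list the lowest, -0.24, and neither passed camera. The order of the lists changes with the scaling, the first place of the glucocorticoid-induced list included.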

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

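Among 52 groups of 4 IgG-IP values tested for a single array far from the other 3 (44 named genes and 8 array measures), 3 stood out, where chance gives about 2.6. For DYNLRB1 the normalised log2 level on IgG-IP replicate 3 was 5.09, above the 4.38 to 4.49 of the other IgG-IP arrays. For WDR45B the level on IgG-IP replicate 2 was 4.36, below the 4.90 to 4.94 of the others. For RN7SK the level on IgG-IP replicate 4 was 5.02, below 5.47 to 5.54. The 3 values came from 3 different arrays, and no explanation was tested. Groups of 3, as in GR-IP, were not tested in this way.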

How the results depend on the processing

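The 39 called named genes kept their direction in each of 273 values obtained by leaving out 1 array. For all of them the GR-IP and IgG-IP arrays did not overlap, so this was close to fixed beforehand and says little about robustness. Of these values 156 stayed past the threshold, with 33 of the 39 calls ended without GR-IP replicate 2, 27 without replicate 4 and 19 without replicate 3. Among all 944 values of single named genes under an alternative, 652 kept direction and side of the threshold, 242 lost the call, 23 gained it and 27 reversed. Of the 413 higher probes, 262 had no detected IgG-IP array.

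The cause was not tested for the following changes, except where a setting tests fewer probes, uses fewer arrays or adds a size limit. Higher and lower probes numbered 277 and 142 without background correction, 102 and 72 with an offset of 50, 5950 and 0 with median centring, 2318 and 478 with z-scores, and 225 and 285 with cyclic loess. They numbered 340 and 153 without a filter, 40 and 132 when detection on all 7 arrays was required, 1072 and 660 with array weights, 647 and 259 with trend and robust moderation, and 115 and 47 at an absolute log2 fold change of at least 1. An unequal-variance test per probe gave 6 and 0 (846 and 563 unadjusted). Chosen after seeing the data, no between-array normalization gave 6143 and 0, and median centring on the tested probes gave 1060 and 1348. Of the higher and lower calls of the main analysis, 109 and 185 stayed with median centring on the tested probes. Cyclic loess kept 183 and 216, and testing without a filter kept 189 and 75. Leaving out 1 array gave 15 to 507 higher and 0 to 270 lower probes, with 177 and 75 without IgG-IP replicate 1, 256 and 134 without replicate 2, 507 and 270 without replicate 3 and 217 and 110 without replicate 4. At an unadjusted p the count without GR-IP replicate 2 was 1003 and 553. The difference in detected probes ranged from 2537 to 3339 without 1 array, with exact p of 0.0667 or 0.1, the smallest that 6 arrays allow.

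With the replicate number as a block, limma called 245 probes higher and 106 lower, of which 200 and 100 were calls without the block. Whether arrays of the same number belong together is not settled. Deviations of same-numbered arrays from their group means correlated across probes at 0.13 for number 2, -0.16 for 3 and 0.037 for 4. Of 3 GR-IP arrays 1 correlated best with its own number. Deviations from a mean of so few arrays are tied to each other (-0.81 between GR-IP replicates 2 and 3), so these values cannot decide it. No list passed camera under the block or without any 1 array.

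With median centring the log2 fold change turned for NR3C1 (0.47), FGA (0.075), CENPH (0.16), P2RX7 (0.071), SNHG10 (0.094), CDH2 (0.92), HSP90AA1 (1.16), XRN1 (0.52) and RN7SK (0.67). Without between-array normalization it turned for NR3C1 (0.58), FGA (0.18), CENPH (0.27), MAP1A (0.016), P2RX7 (0.18), SNHG10 (0.20), TP53BP2 (0.088), CDH2 (1.03), HSP90AA1 (1.27), XRN1 (0.63), SNHG3 (0.018) and RN7SK (0.78). With z-scores it turned for NR3C1 (0.048), RPL12 (-0.28) and RN7SK (0.13), and with median centring on the tested probes for RPL36A (-0.070), HSPA1B (-0.31) and ZNF263 (-0.16).

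For the gene lists, 4 shifted up and 2 down with median centring, and also without between-array normalization, where the ribosomal proteins had 0.53 and the nuclear-retained and noncoding list -0.75. Of these, proteasome subunits (0.43), translation factors (0.35) and ZNF genes (-0.34) turned in direction under both settings. With z-scores 0 shifted up and 4 down. Camera's direction turned from up to down for ribosomal proteins (-1.31) and oxidative phosphorylation (-0.55). The other lists were housekeeping genes (-0.33, camera adjusted p = 0.000139) and translation factors (-0.23, camera adjusted p = 0.00844), the latter against their upward shift with median centring. The median shift of the oxidative phosphorylation list was -0.017 after quantile normalization, against an upward direction in camera, and 0.57 with median centring. Requiring detection on all 7 arrays gave 1 list up, the ribosomal proteins (0.16, adjusted p = 0.0299, with a range over the alternatives of 4.35e-26 to 0.988). Lists were not run with an offset of 50, and slide as a block and the transcript GC and length analysis were not run.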

Other observations

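The tests of dilution and of other splits of the arrays were fixed before their results were seen, as was the bound for removing the GC trend, a setting added after seeing the data, and the other tests here were chosen after the results they bear on were seen. The largest single change belonged to a probe named for a ribosomal RNA. The file places it on chromosome 12, and the RNA was amplified from oligo-dT, so which transcript it reads is not settled. The probe for RNA28SN5, the 28S rRNA, which the file lists under a LOC symbol and which was chosen after its values were seen, had an intensity of 400 ± 176 in GR-IP (SD, n = 3) against 56.0 ± 5.37 in IgG-IP (SD, n = 4), with a log2 fold change of 3.06 ± 0.22 (SE, limma adjusted p = 4.26e-05). MED15, a Mediator subunit also chosen after its values were seen, had a probe called higher (at least 1.11-fold, adjusted p = 0.0253) and another called lower (-0.75, adjusted p = 0.0496, with 62.1 in GR-IP and 62.7 in IgG-IP before normalization). The 2 TAF6 probes moved together, with intensities of 189 and 116 in GR-IP against 57.5 and 49.9 in IgG-IP. Among 265 gene ontology terms, an exploratory test added after seeing the data, 0 passed camera after adjustment. The lowest p belonged to ion transport, with 9 of 71 members lower, 0 higher and a relative shift of -0.18 (unadjusted p = 0.000847, adjusted 0.178).

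The first pattern is the brighter upper range of the GR-IP arrays. A scanner setting or overall brightness would raise the background too, but the lower quartile of intensity had a ratio of 1.0045 between the groups (SD of the IgG-IP arrays 0.020 of their mean), while the mean signal had a ratio of 1.92, which argues against it. More polyadenylated RNA held by the GR antibody, and differences in RNA recovery or amplification between the 2 sets of immunoprecipitates, cannot be told apart by this design, since no input RNA or spike-in was analysed here. If equal amounts of RNA were amplified, which the labels leave unclear, the brighter GR-IP signal would follow the polyadenylated share of the RNA and not the amount recovered. The ratio of 1.92 is of intensities that include background, so it measures neither.

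The second pattern is the set of 234 probes called lower. Their median log2 fold change without between-array normalization was 0.19, against 1.44 for all tested probes. This is what flat signal pushed down by quantile normalization would give for part of the set. That the median lay below 1.44 was close to fixed by the choice of these probes. Its standard error of 0.047 is over probes, which share each array's brightness, and does not measure the spread between arrays. It therefore cannot decide against a lower recovery of these transcripts as a set, even as far as intensity follows recovery. Of the 234, 61 had values below 0, none past the threshold. Signal without a present target transcript may account for part of them. Among lower probes whose gene has another probe, that probe was detected on at least 3 IgG-IP arrays for 8 of 76 (10.5%), against 32.9% for tested probes not called at equal IgG-IP intensity, a difference of -22.3 percentage points (95% interval -29.6 to -14.1), in a comparison that replaced one fixed beforehand over all arrays (22 of 76 against 1162 of 2141), which lower GR-IP signal alone would also move. That interval is over probes, which share the same arrays, and does not measure the spread between arrays. Probes called lower were also chosen in part for high IgG-IP signal on these arrays, which matching on intensity may not remove. Relative depletion in GR-IP of the lower transcripts detected on all 7 arrays, 126 probes, stays open.

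The third pattern is the set of 413 probes called higher. Without between-array normalization their median log2 fold change was 1.58, near the 1.44 of all tested probes, so which probes were called rests on the scaling. In limma 1 of the 35 splits of the arrays, the real one with 647 calls, gave as many. That share of 0.0286 is the smallest this design allows. It argues against chance only for a difference between the groups, which their overall signal already showed. The 647 calls include the 234 lower probes, so the share cannot speak for the 413 higher probes by themselves. The count fell to 15 higher and 0 lower without GR-IP replicate 2, a test with fewer arrays. The highest other split gave 396 with IgG-IP replicate 3 on the GR-IP side, the real grouping with 1 array moved. Among the IgG-IP arrays, replicate 3 had the most detected probes. Removing the trend on probe GC content kept 92.0% of the higher calls (380 of 413), which argues against GC content as the whole cause. Among probes detected on all 7 arrays, which hold 34 of the higher calls, 34 were picked anew in some arrays. In the other arrays they had a higher ratio than the brightest probes in 18 of 18 partitions (median ratio 6.72 against 3.78). The partitions reuse the same 7 arrays and are not independent. The result argues against the same RNA mixture at a lower level in IgG-IP as the whole cause there only if signal follows RNA amount alike for all probes, which was not tested. Only 12 to 25 of those picked were among the 34 called. For the other higher probes 20 simulated draws of such a mixture gave at most 0 calls, but the bound fixed beforehand was too lenient to exclude dilution, since the draws used 1 replicate SD of 0.28 log2 units for every array, noise independent between probes and the mean GR-IP profile, so dilution and selective association with GR cannot be told apart there, and association remains a hypothesis.

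A hypothesis that GR-IP signal rises more with probe GC content than IgG-IP signal was not borne out under a rule that asked for a steeper slope on every GR-IP array. The mean slopes differed by 0.015 log2 units per percent GC (exact permutation p = 0.343). GR-IP replicates 2 and 4, at 0.060 and 0.029, lay above the IgG-IP range of 0.014 to 0.026. GR-IP replicate 3 lay below it, at 0.011, and alone decided the outcome. So few arrays cannot exclude a steeper slope in GR-IP. Across tested probes, which are not independent replicates, the fold change had a Spearman rho of 0.144 with GC content.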
